A study of Homo sapiens with 6 samples.

How the data were processed

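Total RNA of HT1080 cells, a line established from a human fibrosarcoma, had been measured on 6 single-channel oligonucleotide arrays of 22283 probe sets. The labels name 3 groups of 2 arrays: cells with the pGUS vector expressing GFP alone (mock, titled GUS), with the vector also expressing an siRNA against MT1-MMP, and with the vector also expressing an siRNA against integrin alpha3. The array numbers 1 and 2 come from the sample titles. Nothing in the labels says that the 2 arrays of a group came from separate cultures, so every p-value measures only the spread between these arrays, which may be technical. The number of arrays limits the precision. No replicate pair held the same values on more than 78 of the 22283 probe sets, so each array counted as 1 replicate.

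The values analysed are the intensity per probe set that the authors deposited, on a linear scale and above 0. From the values, the mean of the middle 96% of probe sets was 250.1 on every array, so the arrays had been scaled to a common level before deposit. The summarisation software, the background method and the detection calls are not given in the sources used here. No further normalization was applied in the main setting.

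Probe sets were named through the platform annotation supplied with the values. Of the probe sets, 19065 had 1 gene symbol, 1043 had several and 2107 had none, and 68 were controls of the array. Of the singly named probe sets, 19059 matched a current gene record by gene identifier, and 0 symbols needed updating. Probe sets with several or no symbols were left out of the gene tests. No genome build is named in the sources used here, so no coordinates are given.

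Values under 1, of which an array held between 2 and 91, were set to 1, and log2(value + 32) was taken. The offset damps changes of dim genes, so a fold on this scale understates them. Probe sets with a mean above the 40th percentile (log2 value 6.31, signal 47.5) were kept. Of several probe sets of a gene the brightest was used, which left 8045 genes from 11828 probe sets. For genes taken by the rule below or fixed in advance, the text gives the other probe sets above the filter where their log2 fold changes differ in sign or by over 1.5 times, a limit set after these values were seen. For list members only the brightest probe set is given. limma 3.58.1 in R 4.3.3 fitted the 3 group means to all 6 arrays (lmFit, then eBayes with an intensity trend), with 3 residual and 5.35 prior degrees of freedom. The contrasts were each siRNA against mock, the siRNAs against each other, and the mean of both siRNAs against mock. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. An SE is that of the log2 fold change, and an SD is that of the signal over the 2 arrays of a group. Figures were drawn with matplotlib 3.10.9.

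The design, the alternatives, the 24 gene lists and the rule for named genes were fixed before the data were examined, except where the text says otherwise. Each list with at least 5 measured genes was tested against all other genes with camera (preset inter-gene correlation 0.01), again with an estimated correlation, and with fry. The p-values of the lists were adjusted over the 24 lists. Single list members were also adjusted over the list alone. A further 5 lists held markers of endothelial, leukocyte, erythroid, epithelial, and smooth muscle and pericyte cells.

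The rule names the 10 largest rises and 10 largest falls of each siRNA against mock, and 5 each way for the other contrasts, among called genes whose arrays did not overlap between groups. Where fewer genes were called, the places were filled by size from genes with an unadjusted p under 0.01 and no overlap, which are named as not past the threshold. Called members of lists past the threshold, up to 4 per list, and 11 genes fixed in advance were added: MMP2, MMP9, TIMP1, TIMP2, VEGFA, THBS1, SMAD1, CD44, ITGB1, ITGA3 and MMP14. Genes of the X-inactivation centre and the Y chromosome were left out.

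The gene and list tests were tested on simulated arrays of the 8045 genes for MT1-MMP siRNA against mock, in 20 sets with 200 changed genes each. They recovered 34.4% of genes changed by 1 on the log2 scale, 93.3% of those changed by 2 and 99.5% of those changed by 3. Among calls, 5.56% were false. A list shifted by -0.5 was called in 20 of the 20 sets with the preset correlation and in 15 with the estimated one. Genes in these sets varied independently, so the sets do not test the preset correlation on lists whose genes move together. Estimated correlations of the real lists ranged from -0.067 (anti-angiogenic factors) to 0.77 (ribosomal proteins). They were 0.22 for the cell cycle list, 0.31 for collagens and 0.41 for hypoxia and glycolysis.

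The alternatives were quantile normalization, a common 75th percentile, offsets of 1 and 100, no filter and a filter at the 60th percentile, the mean of a gene's probe sets, every probe set on its own, eBayes without the trend, fits of only the groups compared, thresholds of 0.1 or of 1.5-fold in addition, the replicate number as a block, and leaving out each array in turn. Cyclic loess normalization and a block with crossed numbers were added after the data were seen.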

Results

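Expression was compared between HT1080 fibrosarcoma cells carrying an siRNA against MT1-MMP, cells carrying an siRNA against integrin alpha3, and mock cells carrying the GFP vector alone, with 2 arrays per group. MT1-MMP, the product of MMP14, is a membrane-anchored collagenase. Integrin alpha3, the product of ITGA3, pairs with integrin beta1 as a laminin receptor. The arrays had median signals between 72.9 and 83.1. The 3' to 5' signal ratios of GAPDH lay between 0.879 and 0.935 and those of actin between 0.850 and 1.01. The 18 spiked hybridisation control probe sets were brighter on the MT1-MMP siRNA arrays, with median folds over the mock mean of 2.31 and 1.30, against 0.929 and 1.08 on the mock arrays and 0.817 and 0.843 on the alpha3 siRNA arrays. Across genes, mock replicate 1 and alpha3 siRNA replicate 2 correlated more closely (r = 0.970) than the arrays within any group (0.965 for MT1-MMP siRNA, 0.964 for mock and 0.952 for alpha3 siRNA), and genes are not independent replicates.

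Each target had its lowest mean signal in the group carrying its siRNA. MMP14 had a mean signal of 2518 ± 773 (SD, n = 2) in mock cells and 764 ± 67.2 (SD, n = 2) with MT1-MMP siRNA, a log2 fold change of -1.65 (SE 0.31, limma adjusted p = 0.139). All 4 probe sets of MMP14 lay lower with MT1-MMP siRNA, by -2.20 to -1.39 on the log2 scale. MMP14 was also lower with alpha3 siRNA, at 1402 ± 569 (SD, n = 2) and a log2 fold change of -0.86 (adjusted p = 0.851, from -1.27 without alpha3 siRNA replicate 2 to -0.44 without replicate 1), with the 4 probe sets between -0.89 and -0.64. ITGA3 had signals of 1139 and 1290 on the mock arrays, 1481 and 1634 with MT1-MMP siRNA, and 148 and 347 with alpha3 siRNA. Its log2 fold change with alpha3 siRNA was -2.25 (SE 0.32, adjusted p = 0.136), and ITGA3 differed between the 2 siRNAs at an adjusted p of 0.0232. Neither target passed the threshold against mock over 8045 genes. ITGA3 passed it with alpha3 siRNA without replicate 2 of that group (log2 fold change -2.79, adjusted p = 0.0155) and with the replicate number as a block (adjusted p = 0.0422).

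**Figure D1:**
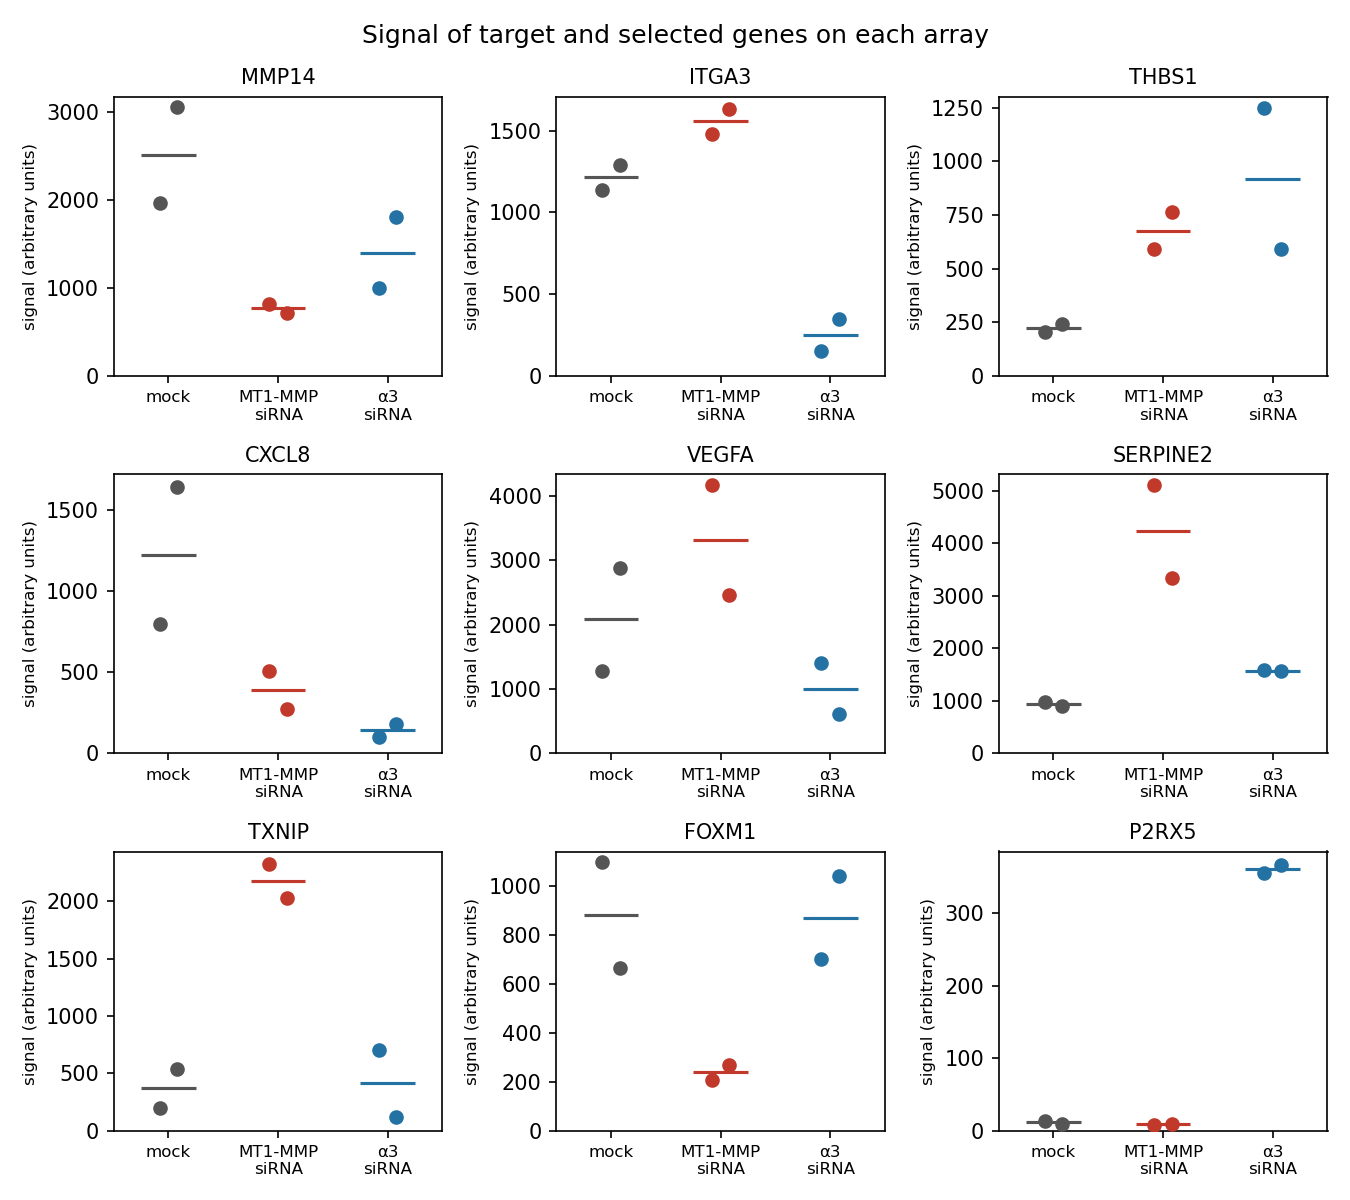
Signal in arbitrary units (linear axis from 0) of 9 genes on each of the 6 arrays, with points for arrays and lines for group means. MMP14 lies at 812 and 717 on the MT1-MMP siRNA arrays against 1971 and 3064 on the mock arrays, ITGA3 at 148 and 347 on the alpha3 siRNA arrays against 1139 and 1290, and P2RX5 at 355 and 367 with alpha3 siRNA against 13.3 and 9.5.

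With MT1-MMP siRNA against mock, genes of the cell cycle and DNA replication fell as a group. The median log2 fold change of the 44 genes was -0.59 (SD 0.38 over genes), 43 of the 44 were below 0, and 19 were lower when adjusted over the list alone (camera adjusted p = 9.54e-16, and adjusted p = 0.385 with an estimated correlation). Collagens and collagen-processing genes rose as a group, with a median of 0.63 (SD 0.39) over 22 genes, 20 of them above 0 and 6 higher when adjusted over the list alone (camera adjusted p = 5.33e-08, and adjusted p = 0.400 with an estimated correlation). Genes of hypoxia and glycolysis also rose, with a median of 0.35 (SD 0.63) over 30 genes and 28 above 0 (camera adjusted p = 1.19e-06, and adjusted p = 0.400 with an estimated correlation). Without mock replicate 1 the collagen median was 0.42.

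The following members are examples chosen after their values were seen, and none of them passed the threshold over all genes. In the cell cycle list, FOXM1, a transcription factor of mitotic genes, had signals of 1096 and 662 on the mock arrays and 206 and 270 with MT1-MMP siRNA. RRM2, a subunit of ribonucleotide reductase, went from 4121 and 2949 to 1123 and 1691, and the helicase subunit MCM2 from 2053 and 1718 to 755 and 1025. In the collagen list, COL6A1 had 385 and 271 on the mock arrays and 658 and 857 with MT1-MMP siRNA, and the prolyl hydroxylase subunit P4HA1 had 838 and 973 against 2143 and 1912. In the glycolysis list, PGK1 had 4263 and 4728 against 8567 and 7389, while aldolase C (ALDOC) differed within the mock pair itself, at 82.9 and 1048, against 4315 and 2221.

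Another 12 of the 24 lists passed the threshold, 10 upward and 2 downward, with camera adjusted p-values from 1.74e-08 to 0.0160, and adjusted p = 0.385 or above with an estimated correlation. Laminins and other matrix glycoproteins rose with a median of 0.30 over 22 genes, 8 of them higher when adjusted over the list alone, among them LAMB1 (343 and 285 on the mock arrays, 962 and 638 with MT1-MMP siRNA). Metalloproteinases and their inhibitors had a median of 0.33 over 18 genes with 5 higher over the list alone, and the 12 anti-angiogenic factors had a median of 0.44 with 3 higher. TIMP3, an inhibitor of metalloproteinases that is on both lists, had signals of 156 and 70.1 on the mock arrays and 478 and 527 with MT1-MMP siRNA. The 7 genes of plasminogen activation and serine proteases had a median of 0.36 with 3 higher over the list alone, cholesterol and fatty acid synthesis 0.42 over 21 genes with 1 higher, and integrins with their tetraspanins 0.35 over 14 genes with 2 higher. Type I interferon response genes (median 0.41, 31 genes, 2 higher), the unfolded protein and amino acid stress response (0.27, 29 genes, 0 higher), and p53 targets (0.21, 18 genes, 1 higher) also passed. All 34 ribosomal protein genes lay above 0, with a median of 0.30. Heat shock proteins and chaperones fell with a median of -0.38 over 16 genes and 6 lower over the list alone, and proteasome genes with a median of -0.32 over 25 genes and 0 lower.

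Several of these lists moved when 1 array was left out or the processing was changed. Type I interferon genes lost their call without mock replicate 1 (median 0.02, adjusted p = 0.371) and without MT1-MMP siRNA replicate 1 (0.097, adjusted p = 0.0683). The unfolded protein and amino acid stress genes lost it without MT1-MMP siRNA replicate 2 (0.11, adjusted p = 0.689) and had 0.48 without replicate 1. The p53 targets lost it without mock replicate 1 (0.11, adjusted p = 0.0667) and without MT1-MMP siRNA replicate 2 (0.14, adjusted p = 0.0716). Without MT1-MMP siRNA replicate 1 the medians were 0.14 for metalloproteinases, 0.22 for plasminogen activation, 0.48 for laminins, 0.11 for ribosomal proteins and -0.18 for the proteasome. Without replicate 2 of that group they were 0.50 for metalloproteinases, 0.68 for plasminogen activation, 0.75 for laminins, 0.69 for anti-angiogenic factors and 0.48 for ribosomal proteins. Without mock replicate 1 they were 0.20 for plasminogen activation, 0.26 for cholesterol and fatty acid synthesis and -0.20 for the proteasome, and without mock replicate 2 the laminins had 0.57. Without a filter, plasminogen activation and serine proteases had a median of 0.039 over 12 genes and lost their call (adjusted p = 0.0891), and the anti-angiogenic factors had 0.20. With every probe set the medians were 0.20 for plasminogen activation, 0.23 for type I interferon, 0.69 for anti-angiogenic factors and 0.74 for laminins. With a filter at the 60th percentile the last 2 had 0.78 and 0.66, with an offset of 100 interferon had 0.27 and anti-angiogenic factors 0.28, and quantile normalization gave 0.17 for plasminogen activation.

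Pro-angiogenic factors did not pass the threshold, with a median of 0.08 over 22 genes and a camera adjusted p of 0.412. Nor did BMP and TGF-beta signalling (median 0.07), focal adhesion and the actin cytoskeleton (0.01), oxidative phosphorylation (0.05), NF-kappaB and inflammatory cytokines (0.08), the mesenchymal and epithelial state (0.15), early response and AP-1 genes (0.23), apoptosis regulators (-0.10), or RNA interference genes (-0.18). With an estimated correlation 0 of the 24 lists passed (lowest adjusted p = 0.385), and fry also passed 0 (lowest adjusted p = 0.167). The ribosomal protein list lost its call under quantile normalization, where its median was 0.03 (adjusted p = 0.420), and kept it under cyclic loess normalization with a median of 0.12 (adjusted p = 0.00153). The hybridisation controls were also brighter in the MT1-MMP siRNA group (2.31 and 1.30), which this comparison does not separate from the siRNA.

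**Figure D2:**
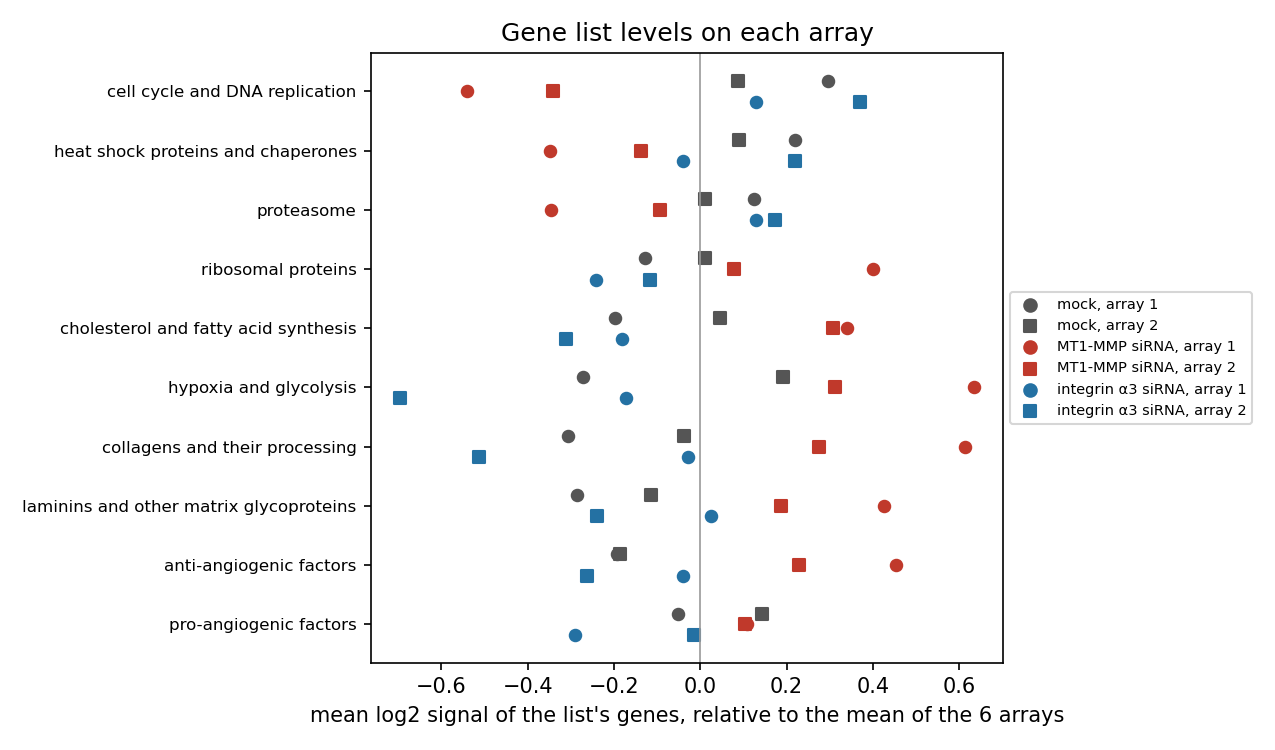
Mean log2 signal of the genes of 10 lists on each array, relative to the mean of the 6 arrays (circles for array 1 and squares for array 2 of a group). The cell cycle list lies at -0.54 and -0.34 on the MT1-MMP siRNA arrays, below the mock arrays at 0.30 and 0.09 and the alpha3 siRNA arrays at 0.13 and 0.37.

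Of single genes, 0 of 8045 passed the threshold for MT1-MMP siRNA against mock in limma, with a lowest adjusted p of 0.0537. At an unadjusted p under 0.05 there were 1160 genes, 544 higher and 616 lower, where chance gives 402. The arrays of the groups did not overlap for 49.9% of genes, against 33.3% by chance. Both chance figures are expectations, and genes that move together can lie far from them in any single set of arrays. The excess alone therefore does not show an effect of the siRNA. At an adjusted p under 0.1 there were 11 genes, and without either alpha3 siRNA array 8 genes passed at 0.05, among them NR4A2, EFNB3, HTRA1, BEX1, SERPINE2 and MRTO4 (adjusted p from 0.0389 to 0.0425). SERPINE2, a secreted inhibitor of serine proteases, had signals of 965 and 900 on the mock arrays and 5107 and 3337 with MT1-MMP siRNA (log2 fold change 2.11, SE 0.22, adjusted p = 0.0537). NR4A2, an orphan nuclear receptor, went from 33.2 and 29.1 to 585 and 329 (2.90, SE 0.34, adjusted p = 0.0537). CDC45, a replication factor, went from 260 and 145 to 16.6 and 21.7 (-2.15, SE 0.27, adjusted p = 0.0537). MRTO4, a ribosome assembly factor, went from 807 and 799 to 234 and 218 (-1.69, SE 0.23, adjusted p = 0.0537).

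The other genes taken by the rule had adjusted p-values between 0.0537 and 0.220. On the higher side were GLUL (log2 fold change 3.20, SE 0.93, with 3 probe sets from 1.57 to 3.20), TXNIP (2.61, with 3 probe sets from 2.06 to 3.18), EFNB3 (2.24, and 0.84 on its other probe set), HTRA1 (2.23), BEX1 (2.14), LRRC17 (2.04), GSTM3 (1.99) and PLAT, the tissue plasminogen activator (1.99). PLAT had 378 and 1683 on the mock arrays against 4853 and 2230, and TXNIP, an inhibitor of thioredoxin, had 198 and 537 against 2323 and 2027. On the lower side were IL24 (-2.05), GAGE1 (-1.93), FOXM1 (-1.73), the polyamine enzyme ODC1 (-1.68), NCAPH (-1.66), MMP14 (-1.65), PRSS3 (-1.62, and -0.79 on its other probe set) and MYBL2 (-1.55). Leaving out 1 array at a time moved GLUL between 2.06 and 4.34, LRRC17 between 1.13 and 2.94, GSTM3 between 1.10 and 2.88, PLAT between 0.95 and 3.02, IL24 between -2.86 and -1.24, and PRSS3 between -2.40 and -0.83. The ends come from the MT1-MMP siRNA arrays for GLUL and from the mock arrays for the others. GAGE1 belongs to a family of near-identical copies, so its probe set cannot be given to 1 gene with certainty.

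Among the genes fixed in advance, CD44, the hyaluronan receptor, had 3735 and 4394 on the mock arrays and 7318 and 6665 with MT1-MMP siRNA (log2 fold change 0.78, SE 0.15, adjusted p = 0.148), and its 7 probe sets above the filter ranged from 0.04 to 0.92. THBS1, an inhibitor of vessel growth, had 204 and 242 against 590 and 762 (1.47, SE 0.33, adjusted p = 0.164), and 4 of its 5 probe sets lay between 1.47 and 1.87 while the remaining one was at 0.01. MMP2 had a log2 fold change of 1.07 (adjusted p = 0.220), ITGB1 of 0.72 (adjusted p = 0.176), and VEGFA of 0.72 (adjusted p = 0.513). VEGFA, the main growth factor of vessels, had 1285 and 2887 on the mock arrays and 4167 and 2465 with MT1-MMP siRNA, and its log2 fold change was 0.15 without mock replicate 1 and 1.30 without mock replicate 2. TIMP1 (0.36), TIMP2 (0.22), SMAD1 (-0.13) and MMP9 (-0.85) had adjusted p-values between 0.440 and 0.816. TIMP1 was at 0.16 without MT1-MMP siRNA replicate 1 and 0.57 without replicate 2. MMP9 was at 127 and 832 on the mock arrays and turned to 0.38 without mock replicate 2. SMAD1 turned to 0.034 without the same array, and TIMP2 to -0.00098 without mock replicate 1.

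With alpha3 siRNA against mock, 2 genes rose and 0 fell in limma. P2RX5, an ATP-gated ion channel, rose from 13.3 and 9.5 to 355 and 367, a log2 fold change of 3.18 (SE 0.23, adjusted p = 0.00407), and stayed at 8.3 and 8.6 with MT1-MMP siRNA. GSPT2, a translation termination factor, rose from 26.9 and 21.3 to 169 and 185 (1.90, SE 0.21, adjusted p = 0.0492). GSPT2 was at 169 and 172 with MT1-MMP siRNA too, and it is closely similar to GSPT1, whose log2 fold changes were -0.54 with MT1-MMP siRNA and 0.18 with alpha3 siRNA. Without either mock array 0 genes passed, without either MT1-MMP siRNA array 1 did, and without alpha3 siRNA replicate 2 there were 9. GSPT2 lost its call on leaving out any 1 of the arrays, with log2 fold changes from 1.83 to 1.97. That includes the MT1-MMP siRNA arrays, which are not in this contrast and left it at 1.90. P2RX5 lost its call on leaving out mock replicate 1 (3.24) or mock replicate 2 (3.12). With 1 array fewer the fit has fewer residual degrees of freedom, so these lost calls do not show that either change rests on 1 array. At an unadjusted p under 0.05 there were 461 genes, against 402 by chance, and the arrays did not overlap for 34.4% of genes, against 33.3% by chance.

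The largest falls by the rule were of genes that did not pass. ACTL8 had 1832 and 1535 on the mock arrays and 36.6 and 231 with alpha3 siRNA (log2 fold change -3.67, SE 0.51, adjusted p = 0.136), and passed without either alpha3 siRNA array (-2.70 without replicate 1, adjusted p = 0.0216, and -4.64 without replicate 2, adjusted p = 0.00117). CXCL8, the neutrophil-attracting and angiogenic chemokine interleukin 8, had 795 and 1647 against 101 and 181 (-2.81, SE 0.40, adjusted p = 0.136), and -1.61 on its other probe set. After ITGA3 came BCL2A1 (-1.64), MSX1 (-1.62), PDE2A (-1.57), PRRC2B (-1.45, and -0.30 on its other probe set), GDF15 (-1.45), STC1 (-1.40, with 3 probe sets from -1.40 to -0.59) and MME (-1.37), with adjusted p-values between 0.271 and 0.834. On the higher side, CDCP1, a transmembrane protein, had 14.4 and 100 against 750 and 509 (3.05, SE 0.51, adjusted p = 0.238). RAB4A (2.53, with 3 probe sets from 1.05 to 2.53), CREB3L1 (2.42, and 0.53 on its other probe set), LYPD1 (1.91), BEX1 (1.86), C1orf115 (1.79) and CDA (1.67) had adjusted p-values between 0.143 and 0.834. Without 1 array, BEX1 ranged from 0.86 to 2.86, CDA from 1.10 to 2.24, MSX1 from -2.31 to -0.92, PDE2A from -2.37 to -0.77, PRRC2B from -2.13 to -0.77, GDF15 from -1.95 to -0.95, and MME from -1.90 to -0.83. The ends come from the mock arrays for CDA and MME and from the alpha3 siRNA arrays for the others, and BEX1 and PRRC2B passed without alpha3 siRNA replicate 2 (adjusted p = 0.0323 for each). THBS1 had 1251 and 589 with alpha3 siRNA, a log2 fold change of 1.81 (SE 0.33, adjusted p = 0.280), with 4 of 5 probe sets above 0 in a range of -0.16 to 2.08, and it passed without alpha3 siRNA replicate 2 (2.34, adjusted p = 0.0323).

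VEGFA had 1400 and 602 with alpha3 siRNA against 1285 and 2887 on the mock arrays, a log2 fold change of -1.04 (SE 0.47, adjusted p = 0.855) that was -1.63 without alpha3 siRNA replicate 1 and -0.45 without replicate 2. MMP9 (-0.72), SMAD1 (-0.25), TIMP2 (-0.22), TIMP1 (-0.16), MMP2 (-0.02), ITGB1 (0.05) and CD44 (0.19) all had adjusted p-values of 0.915 or above. The 7 probe sets of CD44 above the filter differed in sign, from -0.33 to 0.19, with 5 above 0. Without mock replicate 2 the sign turned for MMP9 (0.50), MMP2 (0.29) and TIMP1 (0.0040), without mock replicate 1 for ITGB1 (-0.019), and without alpha3 siRNA replicate 2 for MMP2 (0.42) and ITGB1 (-0.012). From leaving out mock replicate 1 to leaving out mock replicate 2, TIMP2 moved from -0.45 to -0.0015, SMAD1 from -0.42 to -0.089, and CD44 from 0.072 to 0.30.

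Hypoxia and glycolysis genes had a median of -0.26 (SD 0.43) with alpha3 siRNA over 30 genes, 26 below 0 (camera adjusted p = 3.90e-05, and adjusted p = 0.997 with an estimated correlation). The arrays of the 2 groups overlapped, with mean levels of the list at -0.27 and 0.19 for mock and -0.17 and -0.70 for alpha3 siRNA. The alpha3 siRNA arrays differed from each other by 0.525, more than the mean shift of -0.39 in size. Without 1 array the glycolysis median ranged from -0.58 (without alpha3 siRNA replicate 1) to -0.11 (without replicate 2, adjusted p = 0.336), with -0.41 without mock replicate 1 and -0.15 without mock replicate 2 (adjusted p = 0.119). Ribosomal protein genes had a median of -0.15 over 34 genes (camera adjusted p = 0.0371, and adjusted p = 0.997 with an estimated correlation), and lost this call under 11 of 19 alternatives. The ribosomal median was -0.058 without mock replicate 2 (adjusted p = 0.649), -0.089 without alpha3 siRNA replicate 1 (adjusted p = 0.506), -0.20 without replicate 2 (adjusted p = 0.112), -0.066 under quantile normalization (adjusted p = 0.428) and -0.096 under cyclic loess normalization (adjusted p = 0.201). In neither list was any gene lower when adjusted over the list alone. Without alpha3 siRNA replicate 2 the count of lists was 0, without mock replicate 2 it was 1, without mock replicate 1 it was 5, and without alpha3 siRNA replicate 1 it was 6. The cell cycle list had a median of 0.02 and the collagens one of -0.08, with camera adjusted p-values of 0.480 and 0.859. For 8 of the 24 lists, none past the threshold, the median, the mean and the direction of the test differed in sign.

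Between the 2 siRNAs, 112 genes differed in limma, 66 higher and 46 lower with MT1-MMP siRNA than with alpha3 siRNA. The largest differences upward were LRRC17 (838 and 857 with MT1-MMP siRNA, 45.5 and 97.7 with alpha3 siRNA, log2 difference 3.13, SE 0.51, adjusted p = 0.0329), NR4A2 (2.61, adjusted p = 0.0232), ITGA3 (2.60), NDRG1 (2.46, adjusted p = 0.0351) and TSC22D3 (2.32, adjusted p = 0.0232). NDRG1, a gene induced by low oxygen, had 7310 and 4032 against 1257 and 733. The largest downward were P2RX5 (-3.28, SE 0.23, adjusted p = 0.00317), CDCP1 (-3.28, adjusted p = 0.0301), IL24 (-2.94, adjusted p = 0.0411), TOE1 (-2.29, adjusted p = 0.0329) and MYBL2 (-2.26, adjusted p = 0.0312). Of the 112 genes, 108 had log2 fold changes of opposite sign against mock, and for 84 the larger of the 2 was that of MT1-MMP siRNA. Picking genes by this difference itself favours opposite signs. The same number of genes picked from simulated unchanged groups gave 89.4 of opposite sign (80 to 101) and 55.6 larger with MT1-MMP siRNA (45 to 68). The simulated genes varied independently, so these ranges are too narrow to judge genes that move together. Without MT1-MMP siRNA replicate 1 or replicate 2 the count was 0, and without alpha3 siRNA replicate 2 it was 6, where the full set had 1880 genes at an unadjusted p under 0.05.

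The cell cycle list was lower with MT1-MMP siRNA than with alpha3 siRNA, with a median of -0.62 over 44 genes, 5 called lower and 21 lower over the list alone (camera adjusted p = 1.52e-12, and adjusted p = 0.419 with an estimated correlation). The called members with the largest differences were FOXM1 (-1.73), RRM2 (-1.71), CDC6 (-1.68) and MCM7 (-1.40). Hypoxia and glycolysis genes were higher, with a median of 0.72 over 30 genes, 4 called higher and 17 over the list alone (camera adjusted p = 1.81e-10, and adjusted p = 0.419 with an estimated correlation). Their called members were NDRG1, BNIP3L (2.07), the glucose transporter SLC2A3 (1.71) and P4HA1 (1.47). Of the cholesterol list the desaturase SCD (2.14) and MSMO1 (1.42) were called, of the laminin and matrix list LAMC1 (2.09) and NID2, and TIMP3 (2.29) and SERPINE2 (1.38) of the protease lists. In all, 14 of the 24 lists passed with the preset correlation, 11 upward and 3 downward, 0 with an estimated correlation and 0 with fry (lowest adjusted p = 0.103).

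**Figure D3:**
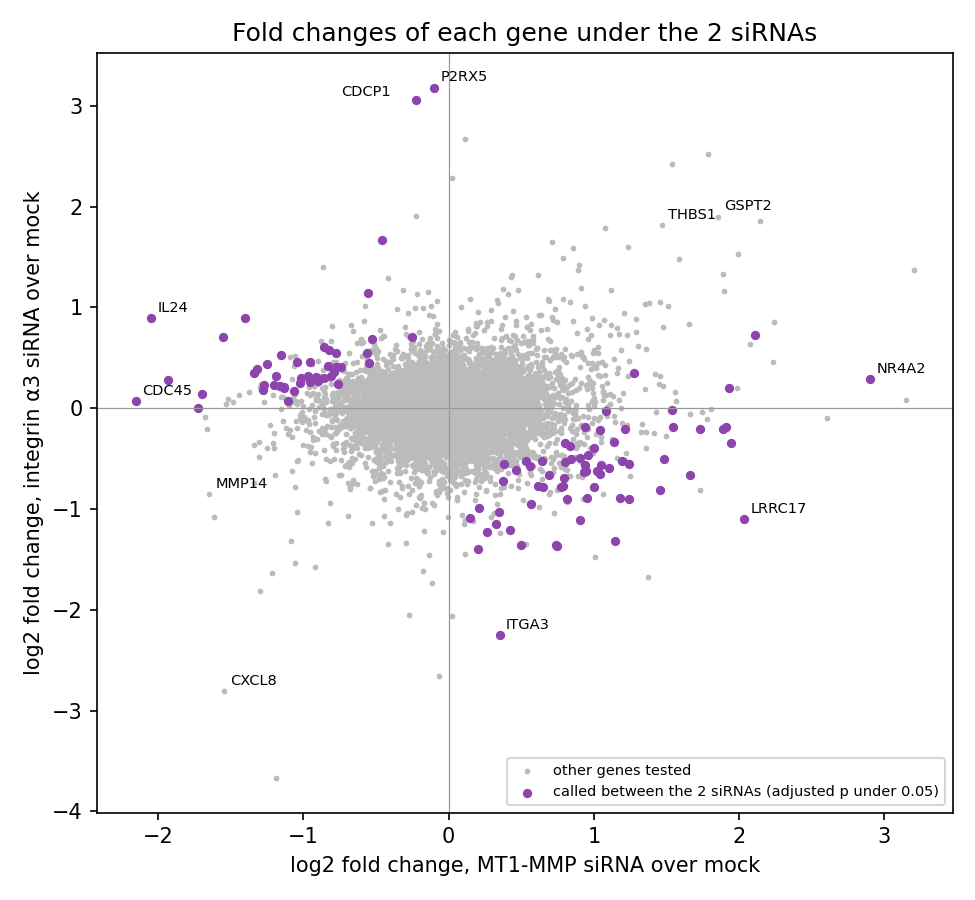
Log2 fold change of each of the 8045 genes with alpha3 siRNA (vertical axis) against that with MT1-MMP siRNA (horizontal axis), both over mock, with the 112 genes called between the siRNAs in purple. Of these, 108 lie in the quadrants of opposite sign, while GSPT2 lies at 1.85 and 1.90.

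The mean of both siRNAs was set against mock. This average does not test whether a change is shared, since 1 siRNA alone can move it. GSPT2 alone was called (log2 fold change 1.88, SE 0.18, adjusted p = 0.0355), and 410 genes had an unadjusted p under 0.05. RAB4A (2.15), BEX1 (2.00), CREB3L1 (1.98) and GSTM3 (1.76) followed on the higher side, and ACTL8 (-2.43), CXCL8 (-2.18), BCL2A1 (-1.43), MMP14 (-1.25) and the DNA repair gene RAD50 (-1.04) on the lower side, none past the threshold. Other probe sets gave 1.44 and 1.05 for RAB4A, 0.47 for CREB3L1, -1.21 for CXCL8 and -0.50 for RAD50, and GSTM3 was at 0.87 without mock replicate 1 and 2.65 without mock replicate 2. Without alpha3 siRNA replicate 1 ACTL8 passed (adjusted p = 0.0323), and without replicate 2 ACTL8 (adjusted p = 0.00454) and BEX1 (adjusted p = 0.0300) did. For 9.66% of genes all 4 siRNA arrays lay beyond both mock arrays, against 13.3% by chance. With the preset correlation 13 of the 24 lists passed, 10 upward and 3 downward. With an estimated correlation 0 passed (lowest adjusted p = 0.492), and with fry 0 (lowest adjusted p = 0.474). Passing here does not mean a change under both siRNAs. Of lists that passed, the cell cycle had medians of -0.59 with MT1-MMP siRNA and 0.02 with alpha3 siRNA, and collagens 0.63 and -0.08. Ribosomal proteins had 0.30 and -0.15, while the unfolded protein and amino acid stress response had 0.27 and 0.15. The mean level of the stress list was -0.093 and -0.13 on the mock arrays. It was -0.14 and 0.35 with MT1-MMP siRNA and -0.095 and 0.11 with alpha3 siRNA, so replicate 1 of neither siRNA lay above the mock arrays. Without mock replicate 1 only 1 list passed, and GSPT2 kept its call only when alpha3 siRNA replicate 2 was the array left out.

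No gene was called in both comparisons with mock. At an unadjusted p under 0.01, 11 genes were higher under both siRNAs, among them THBS1, BEX1, SERPINE2, GSPT2, RAB4A, CREB3L1, VCAN and TGFB2, named after their values were seen. Simulated sets in which all groups, mock included, were unchanged gave a mean of 7.65 (range 2 to 18), and independent lists would share 0.831. Such sets hold only chance numbers of genes at that level, where the data had 361 with MT1-MMP siRNA and 93 with alpha3 siRNA. The simulated means are therefore not the overlap that chance would give for the observed lists. Lower under both were 4 genes, CXCL8, BCL2A1, RAD50 and SLIT2, with a simulated mean of 7.51. FNDC3A and KCNMA1 were the 2 genes with opposite signs at that level, where the simulated mean was 0.2 (highest 2) and independent lists would give 2.06. The mock group holds 2 arrays and was not split, since each part would keep only 1 array, so some of any excess may come from the shared controls. Across genes the fold changes of the siRNAs had a Pearson r of 0.0776, where unchanged groups gave 0.458 to 0.530, and a covariance of 0.0109 against a simulated 0.0445, a difference of -0.0336. Genes are not independent replicates, so the simulated ranges are narrower than genes that move together would give.

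Of markers of other cell types, 0 were called by limma in the comparisons of each siRNA with mock or between the siRNAs. At an unadjusted p under 0.05 there were 1 epithelial and 1 smooth muscle marker with MT1-MMP siRNA, and 1 endothelial, 1 epithelial and 1 smooth muscle marker with alpha3 siRNA. Above the filter were 3 of 11 endothelial, 7 of 12 leukocyte, 1 of 5 erythroid, 4 of 12 epithelial, and 3 of 10 smooth muscle and pericyte markers. The highest were KRT18 (mean signal 2541), MCAM (827), KRT8 (756) and SMTN (748), and TIE1 reached 719 on mock replicate 2 and between 31.4 and 144 on the other arrays.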

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

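The leaving out of MT1-MMP siRNA replicate 1 for the cell cycle list, the comparison of list scores within groups, the comparison of ITGA3 between 2 arrays, the simulation for genes picked between the siRNAs and the cyclic loess normalization were chosen only after the results had been seen. The siRNA carried by the cells, the biological explanation that the design offers for each difference, stays open and was not tested apart from the groups themselves.

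Of the genes called between the siRNAs, 42 had both MT1-MMP siRNA arrays above and both alpha3 siRNA arrays below both mock arrays, and 35 had the reverse. As many genes picked the same way from simulated unchanged groups gave means of 20.7 (13 to 30) and 21.2 (11 to 32). The simulated genes varied independently, so these ranges are narrower than genes that move together would give. They therefore cannot show that 42 and 35 exceed what the picking alone produces. The hybridisation controls, signals outside the gene tests, had median folds over the mock mean of 2.31 and 1.30 on the MT1-MMP siRNA arrays. The first principal component of the genes, with 46.4% of the variance, had scores of 32.5 and 18.3 on the same arrays, -13.3 and 0.77 on the mock arrays, and -12.3 and -26.0 on the alpha3 siRNA arrays, and the relation to the controls cannot be told apart from that to the groups. A separate fit took all 13337 probe sets above the filter, including 1509 with no single gene symbol that the gene tests left out. It called 193 probe sets between the siRNAs, of which 19 had no single gene symbol, 11 higher and 8 lower. For MT1-MMP siRNA against mock it called 17, 1 of them without a single symbol. The gene test called 0 there, and the fit of every singly named probe set 2.

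On the MT1-MMP siRNA arrays the cell cycle genes were lower and the glycolysis genes higher, a difference between groups. After cyclic loess normalization the medians were -0.56 and 0.32, so brightness-dependent differences left by the scaling do not account for them. Without MT1-MMP siRNA replicate 1 the cell cycle median was -0.53, so it does not rest on that array. Arrays of 1 group differed in the cell cycle score by at most 0.242, against a shift of -0.63 between groups, and the labels do not show separate cultures, so a growth state of the cultures apart from the siRNA remains possible. For glycolysis the alpha3 siRNA arrays differed by 0.525, as much as the shift of 0.51, which a growth state at harvest could also produce.

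Ribosomal protein signals were higher on the MT1-MMP siRNA arrays, with a median of 0.30 over 34 genes. Quantile normalization left a median of 0.03 and cyclic loess normalization 0.12, and leaving out MT1-MMP siRNA replicate 1 left 0.11. Random lists of the same brightness had a median of 0.19, and the ribosomal list stood at percentile 96.24 of them. The random lists were drawn from all genes of that brightness, ribosomal protein genes included, which can pull them toward this list. Both tests fit a technical difference that depends on brightness and is largest on replicate 1, and they do not exclude a biological part. The list's median signal of 10310 lay above the 98th percentile of the genes tested on every array (4184 to 4807). Normalization would shrink a real rise of such bright genes too, so its outcome cannot tell a technical from a biological difference.

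Mock replicate 1 was closer to alpha3 siRNA replicate 2 than to the other mock array, a sample near another group. ITGA3 was lower on alpha3 siRNA replicate 2 than on mock replicate 1 by a log2 difference of -1.63, so an exchange of these 2 arrays is excluded by that test. Of the 15 splits of the arrays into 3 pairs, 2 gave as many called genes between a pair of groups as the real one, the real split itself with 112 and another with 308. The splits are too few for a share under 0.05. In that other split the 308 genes lie between the MT1-MMP siRNA pair and mock replicate 1 joined with alpha3 siRNA replicate 2, with 5 genes between the 2 mixed pairs, which points to a structure of the samples or to the small spread of that joined pair (SD 0.377 over genes, the smallest of all pairs), and neither was tested.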

How the results depend on the processing

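Cyclic loess normalization and the block with crossed numbers were chosen after the data had been seen, and for every value below the cause was not tested. With 1 array left out, the array that remains alone in its group is assumed to vary like the arrays of the other groups. Such a fit also has fewer residual degrees of freedom, so a call can be lost though the log2 fold change hardly moves. The signal over background of each array is not given, which limits what can be said of dim genes. The next counts cover the named genes and the lists past the threshold, except each target against mock under its own siRNA. They hold no list value for the estimated correlation or fry, under which 0 lists passed in any comparison. A gene not called in the main setting counts as kept where it stays uncalled in the same direction. Under the other alternatives 1424 values kept their side of the threshold and direction, 62 lost and 33 gained a call, and 2 turned direction. Without 1 array 593 kept them, 102 lost and 21 gained a call, and 10 turned direction.

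Genes called for MT1-MMP siRNA against mock numbered 0, and 11 at an adjusted p under 0.1, 1 under quantile normalization, 3 with an offset of 1, 6 with an offset of 100, 2 with the mean of probe sets, 2 with every probe set, 7 with only the groups compared, and 0 to 8 without 1 array. For alpha3 siRNA against mock the 2 genes became 1 under quantile normalization, 0 with an offset of 1, 1 with an offset of 100, 1 without a filter, 0 with a filter at the 60th percentile, 1 with every probe set, 1 with cyclic loess normalization, 1 with only the groups compared, and 0 to 9 without 1 array. Between the siRNAs the 112 genes became 670 at an adjusted p under 0.1, 69 with an offset of 1, 22 without a filter, 178 with a filter at the 60th percentile, 72 without the trend, and 0 to 83 without 1 array. For both siRNAs against mock the 1 gene became 0 under quantile normalization, an offset of 100, no filter, the 60th percentile and cyclic loess normalization, 2 with every probe set, 2 without the trend, and 0 to 6 without 1 array. The overlap of 0 genes became 1 with the mean of probe sets, and 0 to 1 without 1 array.

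The lists past the threshold became 0 in all 4 comparisons with an estimated correlation and 0 with fry. For alpha3 siRNA against mock the 2 lists became 1 under quantile normalization, a common 75th percentile, no filter, the mean of probe sets, no trend and cyclic loess normalization, 4 with every probe set, and 0 to 6 without 1 array. For both siRNAs the 13 lists became 8 without a filter and 1 to 16 without 1 array, and the lists numbered 13 to 17 for MT1-MMP siRNA against mock and 8 to 13 between the siRNAs.

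With the replicate block the genes called numbered 11 for MT1-MMP siRNA, 4 for alpha3 siRNA and 0 for both against mock, the overlap 1, and the lists for alpha3 siRNA 1. ITGA3 with alpha3 siRNA stayed at -2.25 and passed the threshold (adjusted p = 0.0422). The deviations of the replicates correlated at -0.176, -0.175 and 0.127 between groups, so the number is no evidence of pairing. In the block with crossed numbers the 2 mock arrays exchanged numbers, a pairing that follows the signs of these correlations in the same data. More calls were therefore favoured in advance, and its counts are no evidence for the pairing. Crossed numbers gave 51 genes for MT1-MMP siRNA, 7 for alpha3 siRNA, 599 between them and 0 for both against mock. The overlap was 3, and 1 list passed for alpha3 siRNA.

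Without 1 array ITGA3 with alpha3 siRNA ranged from -2.79 to -1.71 and MMP14 with MT1-MMP siRNA from -1.96 to -1.33. These turned sign without 1 array: with MT1-MMP siRNA, MMP9 (-2.07 to 0.38), TIMP2 (-0.00098 to 0.45) and SMAD1 (-0.29 to 0.034), and with alpha3 siRNA, MMP2 (-0.45 to 0.42), MMP9 (-1.94 to 0.50), TIMP1 (-0.33 to 0.0040) and ITGB1 (-0.019 to 0.12). For both siRNAs the interferon list ranged from -0.10 to 0.39. The medians of ribosomal proteins (-0.0064 to 0.17) and of the unfolded protein and amino acid stress response (-0.027 to 0.27) also turned, while their tests stayed upward. MMP2 with alpha3 siRNA also turned to 0.0061 under a common 75th percentile, and ribosomal proteins for both siRNAs turned to -0.021 under quantile normalization.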

Other observations

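The list in this part was chosen only after the data had been seen, because MRTO4, GRWD1 and other ribosome assembly genes stood among those lower on the MT1-MMP siRNA arrays, and its prediction was written before its values were computed. The hypothesis was that ribosome biogenesis factors as a set are lower with MT1-MMP siRNA, and the list holds none of the genes called between the siRNAs. Of 56 listed genes 43 were measured. Their median log2 fold change with MT1-MMP siRNA against mock was -0.30 (SD 0.29), with 38 below 0 and 5 above. It lay below the range of -0.17 to 0.09 of random lists of the same brightness. The random lists held unrelated genes, while the members of this list moved together (estimated correlation 0.44). Their range is therefore too narrow to judge this list. The following members are examples chosen after their values were seen, and each fell by more than the median. RRS1 (log2 fold change -1.16) had signals of 1028 and 724 on the mock arrays and 315 and 434 with MT1-MMP siRNA. The acetyltransferase NAT10 (-0.84) had 677 and 802 against 369 and 429, and BYSL (-0.86) had 421 and 335 against 150 and 247. The camera p was 2.76e-07 with the preset correlation over 43 genes and 0.258 with an estimated correlation, and 0 of the 43 genes were called by limma.

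With alpha3 siRNA the same list had a median of 0.15, with 34 of 43 genes above 0, and a camera p of 0.000141 with the preset and 0.378 with an estimated correlation. The mean of the list on each array, relative to all arrays, was 0.14 and -0.025 for mock, -0.41 and -0.16 for MT1-MMP siRNA, and 0.077 and 0.38 for alpha3 siRNA. The median of -0.30 is consistent with the hypothesis for MT1-MMP siRNA under the preset correlation alone. The growth state of the cultures was not tested for this list.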
